A study of Mus musculus with 4 samples.

How the data were processed

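Small RNA libraries were made from plasma small extracellular vesicles of wild-type mice, 2 after sham and 2 after myocardial infarction (MI) surgery, all at 12 h. Per the labels' protocols, vesicles were collected from blood by differential centrifugation, RNA was extracted with Trizol and chloroform, and libraries were built with the QIAseq miRNA kit, whose reads carry unique molecular identifiers (UMIs). The deposited values are raw counts, per the file headers: reads per read class, and for each miRNA, PIWI-interacting RNA (piRNA), tRNA and other RNA feature both UMI counts and read counts. No normalization is recorded in the headers. The aligner, its version and the genome build are not given in the sources used here. The tables of mappable but uncharacterised reads held a header and no features, so that class has only its read total. The file headers give the read sets of the second replicate of both groups a shared tag whose meaning is not given in the sources used here. Each file held 1 library, and groups and replicate numbers were taken from the sample titles.

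The deposited tables listed no feature below 10 UMIs. An unlisted feature was therefore entered as 0, and where it was unlisted in both libraries of a group the fold was bounded with 9 UMIs in each. In each table of miRNAs and piRNAs, 1 divider line without values was left out. Of 419 Ensembl transcript identifiers among the tRNA and other RNA features, 407 matched GENCODE M21 (GRCm38), which gave their names and gene types. Positions of miRNA hairpins and genes are those of that annotation, found by gene name, and were not needed for the UMI counts or the tests of features. They were used to find the pairs of miRNAs within 10 kb. UMIs and not reads were used for all tests, since UMIs remove amplification copies. The share of each RNA class had to be taken from reads, because the read class table gives no UMI total. This differs from the plan, and UMI shares of the 4 tabulated classes are given as an alternative.

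UMI counts of miRNAs were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F-test with TMM factors, filterByExpr by group (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment at 0.05. All tests were two-sided. Standard errors are the absolute log2 fold change divided by the square root of F. The same fit was run separately for piRNAs, tRNAs and other RNAs. CPM are UMIs per 1e6 UMIs of the same RNA class, computed from the deposited counts, with the SD over 2 libraries. The 14 miRNA lists for cell types and pathways were fixed before the data were examined. Lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01 on voom values), which left 13. The planned adjustment of single miRNAs was over all tested miRNAs. Members were also adjusted over their own list alone, without correction across lists, so those calls are less strict. Read class shares were compared with an exact permutation test, whose smallest p is 0.333. The confidence level of Poisson intervals was 95%.

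Named miRNAs followed a rule fixed before the data were examined. It took miR-208a-3p and the cardiomyocyte core list, up to 10 miRNAs per direction by p (those not past the threshold said to be so), up to 3 of the most abundant members of each list and up to 8 of the most abundant miRNAs, and in each other class the 2 features with the smallest p per direction. miR-451a, miR-23a-3p as its partner in a ratio, and the pairs of neighbouring miRNAs were chosen after the values were seen.

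Alternatives fixed in advance were read counts, DESeq2 1.42.0 size factors, library size alone, the DESeq2 Wald test, no low-count filter, a filter of 10 counts in every library of 1 group, a replicate block, leaving out each library, a library size over all RNA classes, camera with an estimated correlation, fry, and keeping a miRNA on its first list only. Entering unlisted features at 9 UMIs, testing only features listed in all 4 libraries, summing tRNA copies by anticodon, summing other RNA by gene type, and UMI shares of the 4 classes were added after the data were seen.

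Replicates differed by more than sampling noise, with a chi-square per degree of freedom over 189 miRNAs of 16.0 for the sham pair and 10.5 for the MI pair, against 36.7 to 75.1 between groups. Chi-square grows with depth, and other measures separated the groups less. The SD of the log2 ratio was 0.64 for the sham pair, 0.66 for the MI pair and 0.74 to 0.88 between groups. Spearman correlations were 0.941 and 0.929 within groups and 0.894 to 0.932 between them, so these overlapped. No library was counted as a copy of another. The fit was tested on simulated data, 5 sets of 530 miRNAs of which 200 were changed, drawn from the real means and library sizes with the dispersion of miRNAs listed in all 4 libraries (0.0620), below the 0.364 of the fit to the real counts. For this comparison it called 0.89% of unchanged miRNAs, 25.34% of those changed 2-fold, 69.68% of those changed 4-fold and 87.57% of those changed 8-fold. In simulated sets the liver list, with every member lowered 4-fold, was called in 20 of 20, and 4 of 260 unchanged lists were called. The lists called lower in the real data had median log2 fold changes of only -0.50 and -0.23, so this does not give the power at such sizes. Members were drawn independently, so it does not check the preset correlation either. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.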

Results

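Small RNA was sequenced from small extracellular vesicles (sEVs, membrane particles that cells release into body fluids) of mouse plasma. The vesicles were collected 12 h after sham surgery or after surgery that caused a myocardial infarction (MI, death of heart muscle after its blood supply is blocked). The wild-type mice gave 4 libraries, 2 per group. Unique molecular identifiers (UMIs), short random tags added before amplification, counted each captured RNA molecule once. The sham libraries held 24626952 and 12955563 total reads, and the MI libraries 14455043 and 11872840. Sham replicate 1 gave 377031 miRNA UMIs and sham replicate 2 gave 160451. MI replicate 1 gave 218960 miRNA UMIs and MI replicate 2 gave 135334. In all, 530 miRNA names were listed in at least 1 library and 189 in all 4. A library listed a feature only from 10 UMIs on, so an unlisted feature had between 0 and 9 UMIs. The series title names miR-208a, and the comparison asked which plasma vesicle RNAs differed after infarction. The labels do not say whether the replicates came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

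Of the 4 miRNAs higher after MI at an adjusted p under 0.05, 3 were on the list for cardiac and skeletal muscle. miR-133a-3p, an abundant miRNA of heart and skeletal muscle, rose from 622 ± 69.0 to 4008 ± 539 UMIs per 1e6 miRNA UMIs (CPM, mean ± SD, n = 2 per group), a 6.49-fold difference. miR-133b-3p, its near-identical paralog, rose from 169 ± 9.20 to 1351 ± 231 CPM, or 8.04-fold. miR-208a-3p, which is encoded within the cardiac α-myosin gene Myh6, was listed in neither sham library and reached 504 ± 43.4 CPM after MI. miR-378a-3p, encoded within the metabolic coactivator gene Ppargc1b, rose 5.48-fold from 165 ± 40.0 to 902 ± 42.3 CPM. In the opposite direction, the hepatocyte miRNA miR-122-5p fell from 35077 ± 166 to 11638 ± 544 CPM, which was 2.97-fold lower. miR-146a-5p, a feedback regulator of NF-κB signalling in immune cells, fell 2.33-fold from 4939 ± 181 to 2086 ± 122 CPM. These 4 higher and 2 lower miRNAs were the ones past an adjusted p of 0.05 among 267 tested (edgeR quasi-likelihood test, Benjamini-Hochberg). At an unadjusted p of 0.05, 16 miRNAs were higher and 23 lower.

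The log2 fold change was 2.70 (SE 0.17, adjusted p = 0.00675) for miR-133a-3p and 3.01 (SE 0.21, adjusted p = 0.00675) for miR-133b-3p in the edgeR test. It was 2.46 (SE 0.30, adjusted p = 0.0303) for miR-378a-3p. miR-122-5p had a log2 fold change of -1.57 (SE 0.11, adjusted p = 0.00675) and miR-146a-5p one of -1.22 (SE 0.13, adjusted p = 0.0186). All 6 differences went the same way in both MI libraries against both sham libraries. Reads of miR-133a-3p and miR-133b-3p can be exchanged, because the mature forms are nearly identical, so the split between them is uncertain. The split between directions depended on the scaling, with 4 higher and 4 lower under DESeq2 size factors, 5 and 5 under library size alone, and 3 and 3 under a library size over all RNA classes. Without sham replicate 1, the deepest library, no miRNA passed in either direction, while the log2 fold changes were 2.77 for miR-133a-3p and -1.62 for miR-122-5p (adjusted p = 0.211 for both). The counts of higher and lower miRNAs were 13 and 7 without sham replicate 2, 8 and 12 without MI replicate 1, and 6 and 10 without MI replicate 2.

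**Figure D1:**
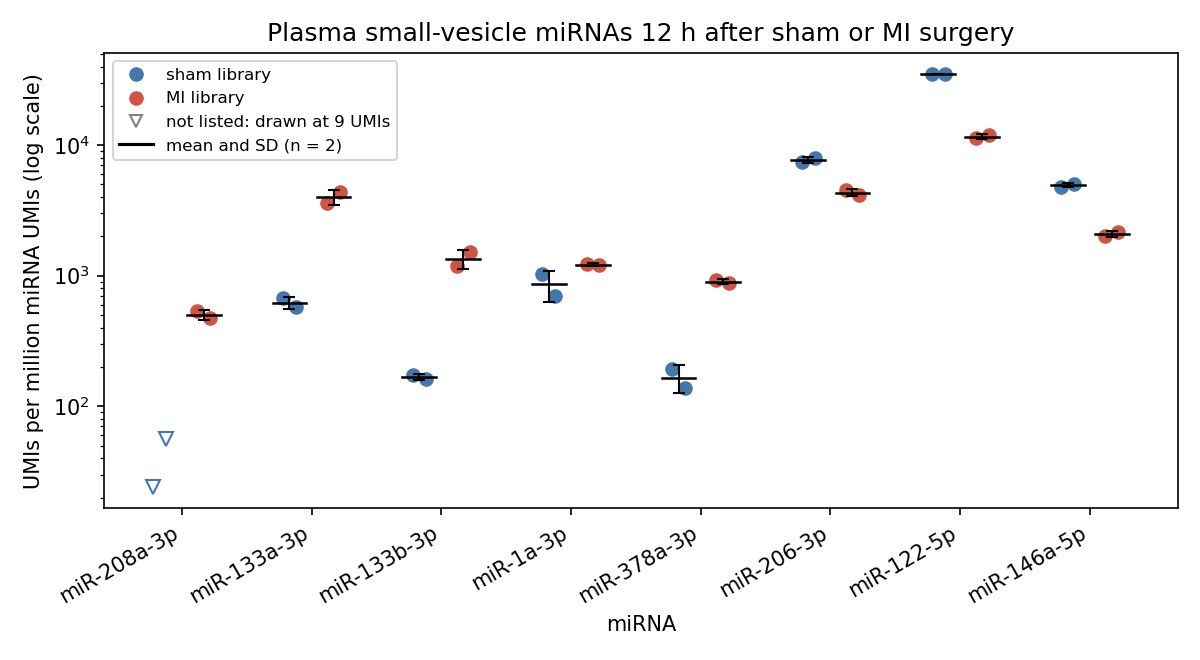
UMIs per 1e6 miRNA UMIs (log axis) of 8 miRNAs in each sham (blue) and MI (red) library, with black bars for the mean and SD (n = 2). Open triangles mark libraries that did not list the miRNA, drawn at 9 UMIs, the highest count that stays unlisted. miR-133a-3p lay at 671 and 573 in the sham libraries and at 3626 and 4389 in the MI libraries.

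miR-208a-3p was counted with 117 UMIs (1275 reads) in MI replicate 1 and 64 UMIs (808 reads) in MI replicate 2. These are 534 CPM (95% exact Poisson interval 442 to 640) and 473 CPM (364 to 604), and the intervals cover counting error only. In the sham libraries it stayed below 10 UMIs, which is at most 23.9 CPM in replicate 1 and 56.1 CPM in replicate 2. Set against 9 UMIs in each sham library, it was at least 12.6-fold higher after MI. The edgeR fit, with its unlisted counts entered as 0, gave an adjusted p of 0.0186. Without sham replicate 1 its adjusted p was 0.211. The passenger strand, miR-208a-5p, was listed in MI replicate 1 alone, with 16 UMIs. The hairpin Mir208a lies on chromosome 14 from 54949060 to 54949142 on the minus strand, in an intron of Myh6 (GENCODE M21 on GRCm38). The related myosin miRNAs miR-208b-3p and miR-499-5p were listed in no library, so each had fewer than 10 UMIs there. Whether either was present below that listing floor cannot be told.

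miR-1a-3p, which shares a primary transcript with miR-133a in muscle, did not follow miR-133a-3p past the threshold. Its level was 862 ± 232 CPM in sham and 1217 ± 28.7 CPM in MI libraries (log2 fold change 0.52, SE 0.26, edgeR adjusted p = 0.529). Mir1a-1 and Mir133a-2 lie 9254 bases apart on chromosome 2 (180389048 to 180389124 and 180398379 to 180398482, plus strand), where no other gene is annotated at either. Mir1a-2 and Mir133a-1 lie 2504 bases apart on chromosome 18 (10785481 to 10785552 and 10782909 to 10782976, minus strand), in an intron of the antisense gene Mir133a-1hg. miR-206-3p, a skeletal muscle miRNA, had 7694 ± 419 CPM in sham and 4331 ± 263 CPM in MI libraries (log2 fold change -0.80, SE 0.16, adjusted p = 0.121). Its hairpin lies on chromosome 1 (20679010 to 20679082), and that of miR-133b lies 3686 bases downstream (20682769 to 20682887), both in exons of the long non-coding gene Gm28653.

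Of the 10 miRNAs on the list for cardiac and skeletal muscle, 6 were tested, 3 rose, none fell and the median log2 fold change was 1.61. Adjusted over the list alone, 3 rose and 1 fell, the latter miR-206-3p. The list of cardiomyocyte core miRNAs had 3 tested members, miR-133a-3p, miR-208a-3p and miR-1a-3p, all of them also on the muscle list, and 2 rose (2 when adjusted over the list alone). Both lists were higher as a set (camera with a preset correlation, adjusted p = 0.00136 each). With an estimated correlation, camera called no list, and the adjusted p = 0.309 for both muscle lists. The estimate was 0.06 for the core list. It was -0.03 for the muscle list and -0.06 for the myeloid list, below the preset 0.01. A higher correlation among members thus does not account for the loss of these last calls. The self-contained test fry gave an adjusted p of 0.0474 for each of the muscle and core lists. The erythrocyte miRNA miR-486a-5p, which is also made in muscle, is on the muscle list and had 34382 ± 2251 CPM in sham and 46052 ± 4498 CPM in MI libraries (adjusted p = 0.341).

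Myeloid miRNAs lay lower after MI as a set. Of the 9 tested members of the myeloid list 1 fell (miR-146a-5p), none rose, and 7 had a negative log2 fold change, with a median of -0.50 (camera, adjusted p = 0.00136). For the myeloid list the adjusted p = 0.309 with an estimated correlation, 0.0597 with fry, 0.159 without sham replicate 2 and 0.0708 with a filter of 10 counts in every library of 1 group. Adjusted over the list alone, 4 fell, miR-146a-5p, miR-24-3p, miR-223-5p and miR-223-3p. miR-223-3p, an abundant neutrophil and platelet miRNA, had 13376 ± 971 CPM in sham and 9399 ± 1912 CPM in MI libraries (adjusted p = 0.260 over all miRNAs). miR-142a-3p, made in most blood cells, had 14238 ± 1582 CPM and 11895 ± 326 CPM (adjusted p = 0.600). None of the 6 tested members of the lymphoid list passed over all miRNAs. Adjusted over the list alone, 1 rose (miR-29c-3p) and 2 fell (miR-342-3p and miR-150-5p), and the set was not called (median -0.30, camera adjusted p = 0.347). miR-342-3p had 9843 ± 1434 CPM in sham and 4278 ± 41.0 CPM in MI libraries, with an adjusted p of 0.0503, and was past the threshold in 11 of 14 alternatives. The alternatives in which it was not past were read counts (adjusted p = 0.0562), a replicate block (0.115) and leaving out sham replicate 1 (0.327).

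The platelet and endothelial list was lower as a set, with no tested member of 10 past the threshold over all miRNAs and 8 below 0 (median -0.23, camera adjusted p = 0.0366). For this list the adjusted p = 0.508 with an estimated correlation, 0.187 with fry, 0.296 without sham replicate 1 and 0.447 without sham replicate 2. Adjusted over the list alone, 2 fell, miR-191-5p and miR-21a-5p. miR-191-5p had 25208 ± 1054 CPM in sham and 14807 ± 743 CPM in MI libraries (adjusted p = 0.0691 over all miRNAs). miR-126a-3p, the main endothelial miRNA, had 13818 ± 2274 CPM and 14645 ± 1819 CPM (adjusted p = 0.895). The call of this list was also lost with read counts (adjusted p = 0.0537), the DESeq2 test (0.0690), the filter of 10 counts in every library of 1 group (0.286), a replicate block (0.0915), a library size over all RNA classes (0.0539), and only miRNAs listed in all 4 libraries (0.0581). It was lost as well when each miRNA was kept on its first list only (0.116). The erythroid list was higher as a set, with 10 of 12 tested members above 0, none past the threshold either over all miRNAs or when adjusted over the list alone, and a median of 0.28 (camera adjusted p = 0.0366). For it the adjusted p = 0.436 with an estimated correlation, 0.204 with fry, 0.260 without sham replicate 2 and 0.466 without MI replicate 1. It was also lost with the DESeq2 test (adjusted p = 0.0740), the filter of 10 counts in every library of 1 group (0.168), the replicate block (0.0915), only miRNAs listed in all 4 libraries (0.0513), and each miRNA kept on its first list only (0.116). With unlisted miRNAs entered at 9 UMIs the direction of its set test turned (median 0.09, adjusted p = 0.984).

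The most abundant miRNA of every library, the red cell miRNA miR-16-5p, had 298042 ± 23657 CPM in sham and 332546 ± 8017 CPM in MI libraries (adjusted p = 0.740). miR-486b-5p had 100634 ± 6665 CPM and 133056 ± 18434 CPM (adjusted p = 0.467). The log2 ratio of the red cell miRNA miR-451a to miR-23a-3p, a measure used to detect haemolysis in plasma, was -1.94 ± 0.02 in sham and -1.03 ± 0.11 in MI libraries (SD, n = 2). This ratio was chosen after the values were seen. Neither miRNA passed on its own, with log2 fold changes of 0.70 for miR-451a (edgeR adjusted p = 0.423) and -0.22 for miR-23a-3p (0.834). Whether haemolysis differed between the groups was not tested. The let-7 family, with 11 tested members of which none passed over all miRNAs or over the list alone, had a median of -0.11 (camera adjusted p = 0.375). Its members let-7i-5p and let-7b-5p had 40227 ± 4624 CPM and 39712 ± 4893 CPM in sham, and 29568 ± 1551 CPM and 35959 ± 894 CPM in MI libraries. Its most abundant member, let-7c-5p, had 62317 ± 9608 CPM in sham and 55249 ± 127 CPM in MI libraries.

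In the liver list 1 of 7 tested members fell, miR-122-5p, which also fell when adjusted over the list alone. The other liver-list miRNAs did not pass. miR-148a-3p had 2836 ± 564 CPM in sham and 2086 ± 306 CPM in MI libraries (adjusted p = 0.600), and miR-192-5p had 1867 ± 357 CPM and 1571 ± 109 CPM (adjusted p = 0.740). The liver set had a median of -0.23 and was not called (camera adjusted p = 0.128). It was called lower with the DESeq2 test (adjusted p = 0.0305), no low-count filter (0.00233), unlisted miRNAs at 9 UMIs (0.0210) and without MI replicate 1 (0.0118). The hairpin Mir122 lies on chromosome 18 from 65248861 to 65248926, in an exon of the long non-coding gene AC157910.3. Of the 5 tested members of the inflammation and hypoxia list 1 fell, miR-146a-5p, and adjusted over the list alone miR-21a-5p fell as well (median -0.68, camera adjusted p = 0.0512). As a set it was called lower with fry (adjusted p = 0.0474), the DESeq2 test (0.0305) and library size alone (0.0409). miR-21a-5p, a miRNA raised in many injured tissues, had 3557 ± 270 CPM in sham and 2188 ± 71.8 CPM in MI libraries (adjusted p = 0.137 over all miRNAs). The hypoxia miRNA miR-210-3p was too low to be tested. Mir146, the hairpin of miR-146a, lies on chromosome 11 from 43374397 to 43374461, and Mir378a on chromosome 18 from 61397835 to 61397900.

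No member passed, over all miRNAs or over the list alone, in the remaining lists. The 8 tested epithelial miRNAs had a median of -0.41 (camera adjusted p = 0.347, and 0.0260 in the lower direction with unlisted miRNAs at 9 UMIs), with miR-205-5p at 786 ± 237 CPM in sham and 404 ± 28.6 CPM in MI libraries. The 5 tested fibroblast and smooth muscle miRNAs had a median of 0.39 (adjusted p = 0.625), and miR-125b-5p stood at 9223 ± 730 CPM and 8635 ± 79.4 CPM. The 10 tested members of the miR-17-92 cluster and its paralogs had a median of 0.25 (adjusted p = 0.375), and the 5 tested members of the imprinted Dlk1-Dio3 cluster one of 0.49 (adjusted p = 0.549). Of the most abundant members, miR-200c-3p had 557 ± 75.5 CPM in sham and 401 ± 70.1 CPM in MI libraries, miR-25-3p 9563 ± 2304 CPM and 11528 ± 1161 CPM, and miR-93-5p 7538 ± 1151 CPM and 8771 ± 992 CPM. miR-382-5p of the Dlk1-Dio3 cluster had 259.8 ± 67.7 CPM and 382 ± 3.66 CPM. Only 1 neuronal miRNA could be tested, miR-128-3p, with 5179 ± 1111 CPM in sham and 3533 ± 190 CPM in MI libraries (adjusted p = 0.403).

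**Figure D2:**
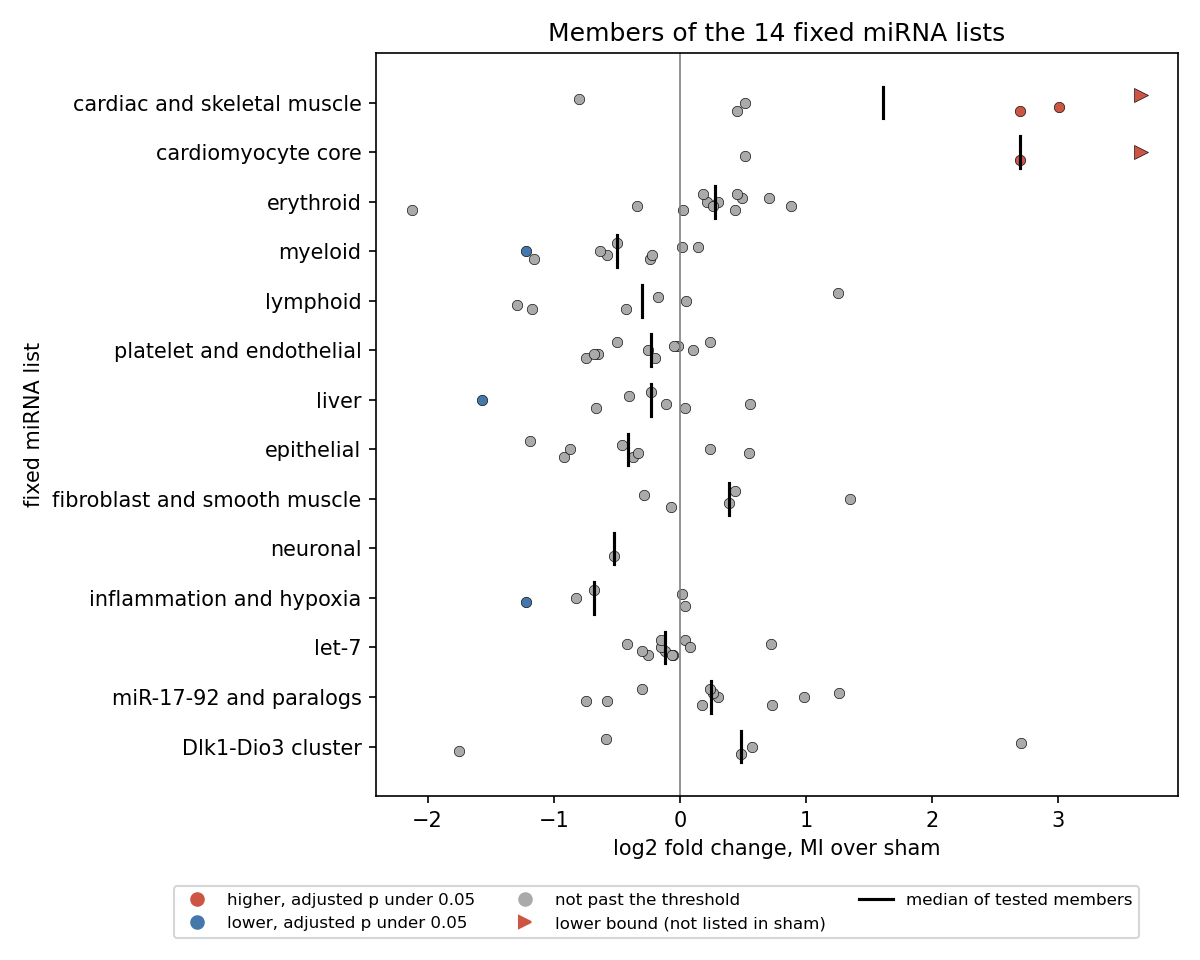
Log2 fold change, MI over sham, of each tested member of the 14 fixed miRNA lists, with a black bar at the median of each list. Red and blue points passed an adjusted p of 0.05 (edgeR), grey points did not, and the triangle is the lower bound of miR-208a-3p. The medians were 2.70 for the cardiomyocyte core list and -0.50 for the myeloid list. Members unlisted in a library enter its count as 0.

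Several further miRNAs came close to the threshold, and some were past it in alternatives (4 of 14 for miR-30a-5p and miR-29c-3p, 6 of 13 for miR-378b and miR-7048-3p, 7 of 14 for miR-191-5p, 5 of 14 for miR-206-3p, 3 of 14 for miR-21a-5p, and 2 of 14 for miR-203-3p and miR-223-5p). miR-30a-5p had 1675 ± 77.0 CPM in sham and 3069 ± 13.5 CPM in MI libraries (adjusted p = 0.0822). miR-29c-3p had 370 ± 50.1 CPM and 878 ± 253 CPM (adjusted p = 0.127). miR-378b was unlisted in both sham libraries and was at least 5.15-fold higher after MI (adjusted p = 0.121 with unlisted counts entered as 0). miR-7048-3p was unlisted in both MI libraries and was at least 4.83-fold lower (adjusted p = 0.0822 with unlisted counts entered as 0). Lower and not past the threshold were also miR-203-3p, with 524 ± 80.2 CPM and 227 ± 23.9 CPM, and miR-223-5p, with 670 ± 92.4 CPM and 298 ± 79.6 CPM. miR-7031-5p, let-7d-3p and miR-6960-5p completed the 10 highest-ranked higher miRNAs, with log2 fold changes of 0.92, 0.72 and 0.71. These 3 were not past the threshold (adjusted p = 0.218, 0.290 and 0.290) and were past it in 0 of 14 alternatives.

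Transfer RNA fragments took the largest part of the UMIs, and their share was lower after MI. tRNA reads were 32.7 ± 5.59% of total reads in sham and 23.2 ± 3.69% in MI libraries. The difference of -9.46 percentage points ranged from -13.4 to -5.51 when leaving out 1 library. miRNA reads were 18.3 ± 4.51% and 15.9 ± 2.45%, a difference that changed sign without sham replicate 1 (0.725 percentage points). Reads of other RNA, which are mainly fragments of ribosomal RNA, were 8.74 ± 0.440% in sham and 13.0 ± 2.53% in MI libraries, with a difference of 4.22 percentage points that ranged from 2.43 to 6.005 when leaving out 1 library. Counted as UMIs, other RNA was 13.4 ± 2.73% of the 4 tabulated RNA classes in sham and 23.4 ± 6.28% in MI libraries. With 2 against 2 libraries an exact two-sided permutation test cannot go below p = 0.333. This permutation test gave p = 0.333 for the tRNA and other RNA read shares and p = 0.667 for the miRNA read share.

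**Figure D3:**
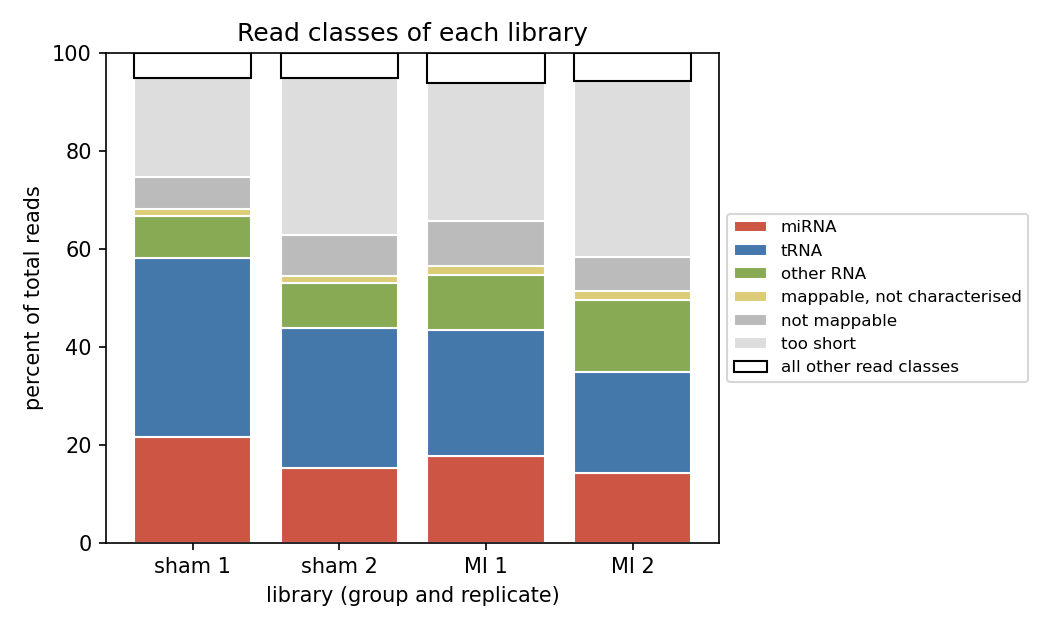
Percent of total reads in each read class for the 4 libraries, as stacked bars from 0 to 100. tRNA took 36.7% and 28.7% of reads in the sham libraries and 25.8% and 20.6% in the MI libraries.

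Among 123 tested tRNA features, 13 rose and 3 fell (edgeR, adjusted p under 0.05). The mitochondrial serine tRNA mt-Ts1 rose from 184 ± 18.7 to 1063 ± 198 UMIs per 1e6 tRNA UMIs (log2 fold change 2.35, SE 0.28, adjusted p = 2.23e-10). It lies at 6870 to 6938 of the mitochondrial genome on the minus strand and overlaps mt-Co1 of the opposite strand, to an extent that was not measured. Of the other 12 features that rose, 5 were valine tRNAs with anticodon CAC, 2 valine tRNAs with anticodon AAC, 4 aspartate tRNAs with anticodon GTC and 1 a serine tRNA with anticodon AGA. tRNA-Val-CAC-2-5 rose from 479 ± 4.36 to 1490 ± 175 per 1e6 (log2 fold change 1.46, SE 0.30, adjusted p = 0.000302). Those that fell were tRNA-His-GTG-2-4, tRNA-His-GTG-2-6 and tRNA-Lys-TTT-1-2. Gene copies of 1 tRNA share their fragments, so calls on single copies are uncertain. Summed over the copies of each anticodon, none of 28 families passed in edgeR, with 2 higher and 2 lower at an unadjusted p of 0.05, and DESeq2 called 2 higher and 3 lower. In edgeR, 4 families were higher and 2 lower with only features listed in all 4 libraries, 1 was higher with library size alone, with a replicate block and with a library size over all RNA classes, and 1 was lower without MI replicate 2. Valine CAC stood at 1333 ± 37.3 per 1e6 in sham and 3081 ± 115 per 1e6 in MI libraries (adjusted p = 0.0558). The counts of single features moved to 22 higher and 1 lower with library size alone, to 2 and 0 with a library size over all RNA classes, to 11 and 10 with only features listed in all 4 libraries, and to 0 and 0 without sham replicate 2. They were 6 and 1 without sham replicate 1, 24 and 8 without MI replicate 1, and 6 and 1 without MI replicate 2.

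Long non-coding RNA fragments made up more of the libraries after MI. Summed over the listed features they came to 7650 ± 715 per 1e6 tabulated UMIs in sham and 21239 ± 2185 per 1e6 in MI libraries, 2.78-fold more. Fragments of ribosomal RNA stood at 121828 ± 26418 and 204330 ± 59183 per 1e6, and the small Y RNAs at 426 ± 34.2 and 369 ± 88.1 per 1e6. Of 169 tested long non-coding RNAs, 108 had a positive log2 fold change within the other RNA class (median 0.65). Among the 81 listed in all 4 libraries it was positive for 43 (median 0.10). Both fits were scaled within a class made mostly of long non-coding RNAs, so these splits do not show how broad the rise was. None of the 233 tested features of this class passed an adjusted p of 0.05 in edgeR (lowest 0.0748), with 51 higher and 16 lower at an unadjusted p of 0.05, whereas DESeq2 called 28 higher and 14 lower. The count rose to 38 higher and 0 lower under a library size over all RNA classes, where the median log2 fold change of the class was 1.47 in place of 0.26. Relative to that class, the smallest p-values belonged to 9230105E05Rik (log2 fold change 2.45, SE 0.33) and Jpx (1.48, SE 0.20), an activator of Xist, and in the lower direction to Gm26546 (-1.67, SE 0.30) and Gm15564 (-1.49, SE 0.26). All 4 had an adjusted p of 0.0748. 9230105E05Rik lies on chromosome 10 in an intron of Hmga2, on the opposite strand, and Jpx, Gm15564 and Gm26546 overlap exons of genes on the opposite strand. The sources used here do not say whether reads were assigned by strand, so fragments of the opposite genes cannot be ruled out for these 4.

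PIWI-interacting RNAs were scarce, with 669 to 982 UMIs per library. None of 21 tested entries passed in edgeR (1 higher and none lower at an unadjusted p of 0.05), and DESeq2 called 1 higher. The smallest p belonged to 1 of 2 entries named mmu_piR_000620, with 84651 ± 30930 UMIs per 1e6 piRNA UMIs in sham and 208171 ± 52455 in MI libraries (adjusted p = 0.0520). The other entry of that name had 207551 ± 80015 and 239150 ± 55942 per 1e6 (log2 fold change 0.57, edgeR adjusted p = 0.730).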

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

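Both results here come from read classes for which no values of single features were given, so only their shares of all reads were compared. The tests of explanations were chosen after the higher shares were seen, and those of mRNA and uncharacterised reads against other RNA after the read totals were known.

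Reads assigned to messenger RNA were a small class that was higher in both MI libraries than in either sham library. They made up 0.180 ± 0.0199% of total reads in sham and 0.327 ± 0.0190% in MI libraries (SD, n = 2), a 1.81-fold difference with an exact permutation p of 0.333, the smallest possible. Mappable reads that were assigned to no RNA class were also higher in both MI libraries, at 1.44 ± 0.0288% in sham and 1.87 ± 0.126% in MI libraries (exact permutation p of 0.333).

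These shares were higher together with long non-coding RNA, which was 2.78-fold more abundant per 1e6 UMIs after MI, against 1.68-fold for ribosomal RNA, 1.71-fold for miscellaneous RNA, 1.88-fold for small nucleolar RNA 1.89-fold for small nuclear RNA, 2.53-fold for the few protein-coding features and 4.01-fold for features without a GENCODE M21 match. For long non-coding RNA the values argue against the floor of 10 UMIs or depth (2.65-fold over the features listed in all 4 libraries). They also argue against an equal rise of all long RNA as its whole cause, since its log2 ratio to ribosomal RNA was higher by 0.74 after MI (-3.98 ± 0.18 in sham and -3.24 ± 0.28 in MI libraries). The 5 long non-coding RNAs with the most UMIs did not carry the rise, which was 3.24-fold without them. They were picked by UMIs and not by their part in the rise, so a rise carried by some other transcripts stays open. Within the other RNA class, 43 of the 81 listed in all 4 libraries had a positive log2 fold change (median 0.10). These 81 were most of the 114 features that set the scaling of that fit, which draws their median toward no change. The split therefore cannot say how many transcripts shared the rise. For the 2 read classes a rise in common with other RNA reads may be enough. Their log2 ratios to other RNA reads differed by 0.31 for mRNA (SD 0.23 in sham and 0.37 in MI libraries) and by -0.18 for uncharacterised reads (SD 0.04 and 0.19). Both differences are less than the larger spread between replicates. Not every read class rose. The separate, small class of ribosomal RNA reads was 0.0557 ± 0.00141% of total reads in sham and 0.0560 ± 0.00566% in MI libraries. Hairpin reads were lower, at 0.01885 ± 0.00219% in sham and 0.0130 ± 0.00325% in MI libraries. RNA carried over from blood or injured cells into the vesicle fraction and a release of longer RNA in vesicles after infarction were not tested and stay open.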

How the results depend on the processing

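The 6 miRNA calls kept their sign under all 14 alternatives in which they were tested, with log2 fold changes of 2.49 to 2.92 for miR-133a-3p, 2.79 to 3.03 for miR-133b-3p, 2.18 to 2.70 for miR-378a-3p, -1.76 to -1.55 for miR-122-5p and -1.41 to -1.14 for miR-146a-5p. All 6 stayed called under all but 3 settings (miR-208a-3p cannot be tested among features listed in all 4 libraries). The exceptions were read counts (5, without miR-133b-3p, adjusted p = 0.0508), a library size over all RNA classes (5, without miR-378a-3p, adjusted p = 0.0561) and leaving out sham replicate 1 (0). Leaving out 1 library leaves an arm with 1 sample, which is assumed to vary like the other group. The adjusted p of miR-208a-3p was 0.211 without sham replicate 1, and ranged from 6.87e-20 to 0.211 when leaving out 1 library and from 6.06e-19 to 0.0325 over the other alternatives. The cause of these changes was not tested. The common dispersion was 0.364 over the tested miRNAs with unlisted values entered as 0 and 0.0620 among miRNAs listed in all 4 libraries; no test separated the zeros from the low levels of the further miRNAs. The listing floor limits what can be said of any feature under 10 UMIs.

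Against 4 higher and 2 lower miRNAs, there were 13 and 15 with the DESeq2 Wald test, 8 and 12 with no low-count filter, 4 and 4 with DESeq2 size factors, 5 and 5 with library size only, 5 and 5 with unlisted features at 9 UMIs, and 5 and 8 with only features listed in all 4 libraries. Leaving out 1 library gave 0 to 13 higher and 0 to 12 lower. Against 13 higher and 3 lower tRNA features, there were 2 and 0 with read counts, 22 and 1 with library size only, 2 and 1 with the DESeq2 Wald test, 6 and 1 with no low-count filter, 2 and 0 with library size over all RNA classes, 5 and 2 with unlisted features at 9 UMIs, and 11 and 10 with only features listed in all 4 libraries. Leaving out 1 library gave 0 to 24 higher and 0 to 8 lower. Against 0 and 0 other RNA features in edgeR, there were 28 and 14 with the DESeq2 Wald test, 25 and 10 with no low-count filter, 47 and 8 with at least 10 counts in every library of 1 group, 38 higher with library size over all RNA classes, 33 and 5 with unlisted features at 9 UMIs, and 24 and 14 with only features listed in all 4 libraries. Against 0 piRNAs, 1 was higher with the DESeq2 Wald test, 1 with the replicate block, 1 with library size over all RNA classes and 1 with only features listed in all 4 libraries, and 0 to 1 when leaving out 1 library. The scaling moved the median log2 fold change of tRNA features from 0.08 to 0.24 with library size only and -0.03 over all RNA classes, that of piRNAs from 0.17 to -0.04 with library size only and 0.69 over all RNA classes, and that of other RNA from 0.26 to 0.67 and 1.47. The cause of these shifts was not tested, except that the filters change how many features are tested.

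Against 3 higher and 2 lower lists, there were 0 and 0 by camera with an estimated correlation, 1 and 1 with a miRNA kept on its first list only, and 1 and 1 with only features listed in all 4 libraries. The lower lists numbered 1 with read counts, 0 with at least 10 counts in every library of 1 group, 1 with library size over all RNA classes, 4 with unlisted features at 9 UMIs (myeloid, platelet and endothelial, liver, epithelial) and 1 with fry in place of camera (the inflammation and hypoxia list, adjusted p = 0.0474). They numbered 3 each with the DESeq2 Wald test (myeloid, liver, inflammation and hypoxia), library size only (myeloid, platelet and endothelial, inflammation and hypoxia) and no low-count filter (myeloid, platelet and endothelial, liver). Leaving out 1 library gave 2 to 3 higher and 0 to 3 lower. The erythroid set turned direction with unlisted features at 9 UMIs (median 0.0926, adjusted p = 0.984). The miRNA share, lower by 2.47 percentage points after MI (a difference of -2.47), was 0.583 points higher as UMIs of the 4 classes and ranged from -5.66 to 0.725 when leaving out 1 library. The other RNA share difference of 4.22 points became 10.3 with reads of the 4 RNA classes as denominator and 9.99 with UMIs of the 4 classes. The tRNA share difference of -9.46 points ranged from -13.4 to -5.51 and that of other RNA from 2.43 to 6.005 when leaving out 1 library. The causes were not tested.

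The replicate block gave 4 higher and 2 lower miRNAs (adjusted p = 0.0287 for miR-208a-3p), 17 and 3 tRNA features, 0 and 0 other RNA features, 1 higher piRNA, and 1 lower list in place of 2. Among the higher lists, the erythroid list was lost under this block (camera adjusted p = 0.0915). There are only 2 pairs, and the labels do not say that numbers pair libraries. The second replicates share an unexplained header tag, so a preparation common to both is not excluded. Across 189 miRNAs, which are not independent replicates, the deviations of same-numbered libraries correlated at r = 0.253 (Spearman 0.134).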

Other observations

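The tests in this part were chosen after the patterns were seen, and only the gaps of the other neighbouring miRNAs were unknown when the tests were written down.

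Several further features did not pass the threshold. miR-29c-3p had a log2 fold change of 1.26, and its cluster partner miR-29b-3p one of -0.18. miR-145a-5p, a smooth muscle miRNA, stood at 1.35 (SE 0.61, edgeR adjusted p = 0.466). The 2 Y RNAs of the other RNA class, which bind the Ro60 protein, had log2 fold changes of -1.65 for Rny1 and -1.16 for Rny3 relative to that class (adjusted p = 0.0748 and 0.0954). Relative to the same class, the long non-coding RNA Dnm3os, the host of miR-199a and miR-214, stood at -1.59 (adjusted p = 0.0954). Gm4117 stood at 1.35 (adjusted p = 0.0748). The class itself took 13.4% of tabulated UMIs in sham and 23.4% in MI libraries. As a share of all tabulated UMIs, the Y RNAs together were 0.87-fold of sham after MI, with overlapping libraries. With a library size over all RNA classes, 38 features of the class were higher and 0 lower. The values for Dnm3os and the Y RNAs therefore do not show falls of that size in the libraries as a whole. All features named here were chosen after their values were seen.

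In the clusters that encode miR-133a with miR-1a and miR-133b with miR-206, the miR-133 member was called higher after MI and the partner was not. miR-1a-3p still had a log2 fold change of 0.52, with both MI libraries above both sham libraries. That of miR-206-3p was -0.80. The log2 ratio of miR-133a-3p to miR-1a-3p within a library, which no scaling can change, was -0.45 ± 0.23 in sham and 1.71 ± 0.23 in MI libraries (SD, n = 2), a difference of 2.16 that argues against library size or scaling. The gap in log2 fold change was 2.18 and 3.80 for the muscle pairs and at most 1.49 (median 0.45) for 43 other pairs within 10 kb, but the muscle pairs were picked after their values were seen, so the usual divergence of neighbours stays open. miR-133a reads counted as miR-133b also stay open, since the log2 ratio of miR-133b-3p to miR-133a-3p was higher by only 0.31 after MI, with a counting error of 0.20. A hypothesis that was not tested is that heart muscle may release miR-133 in vesicles in preference to miR-1; no sample here measures the tissues.

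miR-122-5p fell while the other liver-list miRNAs did not pass the threshold. A larger share taken by abundant miRNAs would lower most others alike, but the 189 miRNAs listed in all 4 libraries had a median log2 change of 0.0244, against -1.59 for miR-122-5p. Library depth would need a change of 2.65 on the log2 scale per doubling of depth, whereas the larger slope within a group was -0.14. Less liver-derived RNA as a whole may account for the fall and cannot be told apart from a change in miR-122 alone, because the 6 other members, which other tissues also make, had a median of -0.17 and ranged from -0.66 to 0.56.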
